A study of Mus musculus with 2 samples.

How the data were processed

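TCF12 ChIP-seq peak lists of 2 biological replicates of MEL cells were used. The replicate numbers came from the labels, and both samples formed 1 group, so no comparison between groups was made. P-values therefore measure spread over sites, genes or shuffles, not over samples. The labels name a control experiment, and the notes beside the files give the output type, the genome build and the files each list was derived from. The aligner, the peak caller and the reproducibility threshold are not given in the sources used here.

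The authors deposited a relaxed list for each replicate and for both replicates pooled, 2 sets of reproducible peaks (optimal and conservative) derived from these on mm10, and a list on mm9 derived from alignments of both replicates. Each deposited list gives a signal value per peak, whose formula is not given in the sources used here, so it was used only to rank or describe peaks within a list. The authors' score column of the reproducible sets starts at 537 and was not used to select peaks. The last value column of the deposited pooled and reproducible lists is on a log10 scale, the −log10 of a q-value by the file format. In the optimal set 156 entries had a value just below 0, of which 23 remained as sites of their own, and none was removed. On the deposited mm9 list the −log10 q-values started at 2.77. Read counts were not used here, so depth is unknown, and intervals over peaks cover counting error only.

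Overlapping entries of a set were merged into sites, keeping the strongest summit. Sites on the 19 autosomes and on X and Y were kept. The reference genome was NCBIM37 with its GENCODE transcripts, which is mm9, and a RefSeq table of GRCm38 genes gave the ends of genes on mm10. Each list was used only with annotation of its own build, checked by the share of sites near start sites (21.2% for mm10 sites with GRCm38 genes against 6.78% with NCBIM37), and no coordinates were converted. The GRCm38 table had no strand, which was taken from the gene of the same name on NCBIM37. Of 21678 protein-coding genes, 1186 without strand were left out, Hbb-bs and Hbb-bt among them. Another 209 genes, placed before the first peak of their chromosome, were left out beforehand.

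The plan, fixed before the data were examined, named the optimal set for all results. As sequence and full transcripts were at hand for mm9 only, motifs, spacing and genomic annotation used the mm9 list instead, and motif content by strength used 10 bins of equal size of that list. A class for other exons was added to the annotation. Shuffles on mm10 ran over stretches covered by the relaxed lists, leaving out gaps over 50 kb.

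Replicates were compared by overlap of at least 1 bp among the 38384 strongest peaks of each, with 5 shuffled placements as background. Promoters were within 1 kb of a start site, tested against 100 shuffles. Motifs were searched on both strands within 50 bp of summits and in windows 300 bp to each side. Summits and right-hand flanks were compared by exact McNemar tests, Benjamini-Hochberg adjusted over 20 motifs, and intervals of ratios came from 1000 bootstraps over sites. Spacing used 100 bp around summits and exact binomial tests over 31 spacers in each order. Classes of sites and gene lists were compared by two-sided Fisher's exact tests, and gene lists also with 10000 random lists matched on gene length. P-values below 1e-300 were written as 1e-300.

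Genes were named by a rule fixed before the data were examined: Tcf12, Tal1, Tcf3, Lyl1, Lmo2, Ldb1, Gata1, Cbfa2t3, Klf1 and the globin genes always, of each other list up to 4 members with the strongest sites and up to 2 with none, the 10 strongest sites, and the 5 genes with the most sites. For Gata1, Cbfa2t3, Alad, Add2, Epor and Rpl36a, the sites around the start on mm10 were not analysed here. They were singled out after their values were seen, because the mm10 lists had few or no entries there while the mm9 list had sites, and they remain in the denominators.

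Scripts were tested on simulated data. A spacer of 9 bp planted in 3000 sequences was recovered as the only one called, and 3.70% of random lists of 20 genes had a p under 0.05. Lists of 20 genes with 85% of genes near sites had an unadjusted p under 0.05 in 93.2% of draws. Smaller lists and adjusted p-values were not simulated. Copies of 1 sequence diverged by 20%, planted as 10% of 3000 sequences, were all found. The test of density on chromosome 15 was first run in another form, with a tolerance in gene number and without X, and then replaced by the form written in advance. The alternatives tried were the conservative set and smaller peak sets, each replicate left out, other overlaps, windows and distances, other backgrounds, and the mm9 list. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.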

Results

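TCF12 binding was mapped by ChIP-seq in MEL cells, a mouse erythroleukemia line of virus-transformed red cell precursors. TCF12, also called HEB, is a basic helix-loop-helix E protein that binds E-box DNA, often as the partner of tissue-restricted proteins such as TAL1. The 2 samples were biological replicates of 1 group, and no other condition or untreated group was compared. The data were peak lists, so the number of reads behind each peak is unknown. Each replicate had a relaxed list of 300000 entries on mm10. The set of reproducible peaks that the submitters call optimal held 38384 entries, which merged into 36901 sites on the main chromosomes. A second set, called conservative, held 34501 entries, and a separate list on mm9 held 25403 entries, or 25357 sites.

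The first comparison asked how far the replicates gave the same peaks. Among the 38384 strongest peaks of replicate 1, 70.9% overlapped one of the 38384 strongest of replicate 2 (Wilson 95% interval 70.5% to 71.4% over peaks). Positions shuffled within chromosomes shared 1.06%. All of the 1000 strongest peaks of replicate 1 were shared, against 31.3% of the 1000 weakest of those compared. Of the replicate 1 peaks that were not shared, 77.9% overlapped an entry further down the full replicate 2 list. Across the 35657 of 36901 optimal sites found in both full lists, Spearman's rho of the authors' signal value was 0.657 (bootstrap 95% interval 0.651 to 0.664). This is a correlation over sites, which are not independent replicates and were called reproducible from these same replicates. The conservative set overlapped 78.9% of the optimal set (78.5% to 79.3%), and the optimal entries outside it had a median signal of 20.7, against 46.2 for those inside. The sets were not nested, since 4209 conservative entries overlapped no optimal entry.

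The strongest sites lay both inside and outside genes. The strongest of all, at chromosome 5, 36736047 to 36736333 (mm10), had a signal value of 474.6 and lay outside any protein-coding gene, with Bloc1s4 as the nearest start site, 12491 bp away. The site ranked 2 was inside Slc16a10, an aromatic amino acid transporter gene, at chromosome 10, 40131750 to 40132085. The site ranked 3 was inside Nprl3 at chromosome 11, 32245624 to 32245989, in the region that holds the distal enhancers of the alpha-globin genes, and it ranked 5 in replicate 1 and 31 in replicate 2. The site ranked 5, at chromosome 4, 117830082 to 117830443, had as its nearest start site that of Slc6a9, a glycine transporter gene. Glycine is a substrate of heme synthesis. The other sites among the 10 strongest had Asic1, Slfn14, Pik3cg, Foxo1, Gse1 and Ube2l6 as the nearest protein-coding start sites. Those nearest Foxo1 and Gse1 lay inside these genes, that nearest Ube2l6 lay inside Smtnl1, 13224 bp from the start of Ube2l6, and that nearest Pik3cg lay in no protein-coding gene, 65292 bp from its start. Gse1 also held the most sites of any gene, 32 in the gene and 10 kb around it, followed by Nfia with 30, Babam2 and Prkce with 28 each and Bbs9 with 25. These are long genes, and their densities ranged from 5.35 to 8.58 sites per 100 kb. On mm10 only the ends of genes were used, so exons and introns are not told apart there.

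At the alpha-globin genes on chromosome 11, the optimal set held 17 sites in the cluster and 100 kb around it. Besides the site in Nprl3 described above, the sites at 32265231 to 32265414, at 32269069 to 32269236 and at 32250994 to 32251170 had signal values of 277.1, 208.7 and 204.4. The first and the last of these lie within the ends of Nprl3, and the middle site lies 7462 bp before Hba-x, the embryonic alpha-like gene. Within the cluster itself lay a single weak site, at 32293520 to 32293823, ranked 23057 with a signal value of 31.3. It was the only optimal site within 10 kb of the start sites of Hba-a1, Hba-a2, Hbq1a and Hbq1b, and it lay 10000 bp from that of Hba-a1. At the beta-globin genes on chromosome 7, 15 sites lay in the same distance. The strongest, at 103910041 to 103910444, ranked 130 and lay 57013 bp upstream of the start of Hbb-y, the embryonic beta-like gene. The site closest to Hbb-y, at 103854736 to 103854973, ranked 1454 and had -1660 bp as its position relative to the start, a negative value being upstream. The optimal set had no site within 10 kb of the start sites of Hbb-bh1 and Hbb-bh2, whereas the replicate 2 list did. Sites also lay beyond the other end of the cluster, next to Hbb-bt. The closest were 215 and 838 bp outside it, ranked 3398 and 1574. Hbb-bs and Hbb-bt had no strand, so sites near their starts were not counted.

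**Figure D1:**
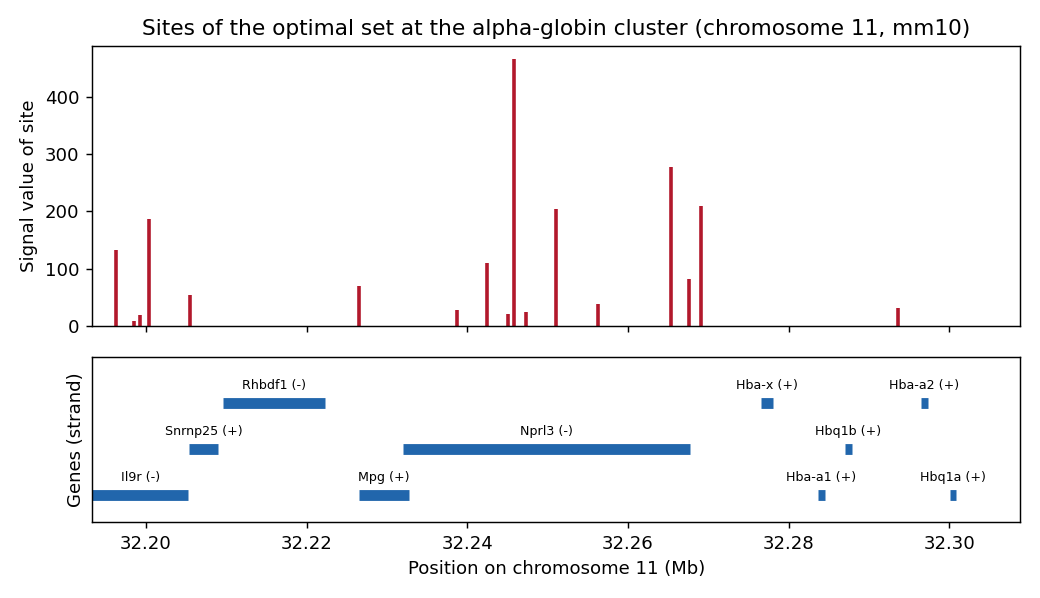
Sites of the optimal set around the alpha-globin cluster on chromosome 11 (mm10). Bars give the authors' signal value at each site's position in Mb, and boxes below give the genes with their strand. The site in Nprl3 has a signal value of 465.1, and the single site within the cluster one of 31.3.

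Genes of erythroid transcription factors commonly had TCF12 sites near their own start sites. Within 1 kb of the start 14 of 20 had a site (70%), against 35.5% of other genes. The counts of sites below are within 10 kb. Tal1, whose product pairs with E proteins in blood cells, had 3 sites within 10 kb, the strongest at chromosome 4, 115056562 to 115056806 (mm10), 261 bp past its start and ranked 693. Lyl1, a close relative of Tal1, had 4 sites, and the strongest, at chromosome 8, 84701550 to 84701811, ranked 203. Klf1, the erythroid Kruppel-like factor, had 4 sites, with the strongest at chromosome 8, 84901178 to 84901431, ranked 452. Lmo2 and Ldb1, which encode a bridging protein and a dimerizing protein of the same complexes, had 5 and 4 sites, with the strongest ranked 1764 and 5839. These strongest sites of Lmo2 and Ldb1 lay at -7 and -8346 bp relative to the start. Gata2 had 6 sites, of which the strongest ranked 328 and lay 9305 bp past its start. Tcf12 and the related E protein gene Tcf3 had 1 site each within 10 kb, at their start. These were at chromosome 9, 72111671 to 72111974, and at chromosome 10, 80433708 to 80434011, ranked 7923 and 11066. Counted over the gene and 10 kb around it, Tcf12 had 19 sites and Tcf3 had 4.

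Of 17 gene lists fixed before the data were examined, 5 had a site within 10 kb of a start site more often than other protein-coding genes, of which 50.3% of 20492 had such a site. These were red cell membrane genes (16 of 19, 84.2%, adjusted p = 0.0188), iron handling genes (12 of 12, 100%, adjusted p = 0.00415), erythroid transcription factors (17 of 20, 85%, adjusted p = 0.0146), autophagy and mitochondrial clearance genes (11 of 12, 91.7%, adjusted p = 0.0216) and ribosomal protein genes (72 of 80, 90.0%, adjusted p = 8.96e-13), by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over lists. The membrane genes with the strongest sites were Gypa, the gene of glycophorin A, with its strongest site at rank 193, then Tmod1 at 416, Rhd at 421 and Epb41 at 484. Among the iron genes, Slc11a2, which encodes an iron importer, had a site at rank 300 at chromosome 15, 100419977 to 100420212. Tfr2, Slc40a1 and Fth1 followed at ranks 417, 718 and 2565. Among the autophagy genes, Bnip3l, known for the clearing of mitochondria in maturing red cells, had a site at rank 1517, Ulk1 at 2345, Wipi1 at 2673 and Map1lc3b at 6054, while Gabarapl1 had none in the optimal set. The ribosomal protein genes with the strongest sites were Rpl3 at rank 307, Rpl13a at 541, Rpl26 at 1157 and Rpl8 at 2598. In this last list Rpl10l had none. Ribosomal protein genes are not an erythroid list, yet their share exceeded those of membrane genes and erythroid factors. Iron and autophagy genes had higher shares. Expression was not measured, so these calls do not separate binding at erythroid genes from binding at active promoters. With only sites over 1 kb from start sites, the ribosomal share was 45%, against 66.7% to 91.7% in the other lists named. This difference was not tested.

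Heme synthesis genes had a site in 10 of 12 cases (83.3%), which did not pass after adjustment (adjusted p = 0.0819, Fisher's exact test). With 10 of 12 in each replicate's list too, the call depended on the replicate (adjusted p = 0.101 for replicate 1 and 0.0435 for replicate 2, Fisher's exact test). Abcb10 had its strongest site at rank 30, at chromosome 8, 123988644 to 123988981 (mm10), Alas2, the first enzyme of heme synthesis in red cells, at 426, Fech, the last enzyme, at 548, and Ppox at 586. Among the 5000 strongest sites alone the list did pass, with 9 of 12 genes (adjusted p = 1.11e-07, Fisher's exact test). Globin genes had a site in 6 of 8 cases (adjusted p = 0.366, Fisher's exact test), but against 10000 random lists matched on gene length, globin genes being short, the list passed (adjusted p = 0.0068). Hba-a1, Hba-a2, Hbq1a and Hbq1b all counted through the same weak site. Both tests treat such neighbours as independent genes, and the random lists were not matched on position, so neither p allows for this. The globin list also depended on a single replicate: 2 of 8 genes had a site in the replicate 1 list and 8 of 8 in the replicate 2 list. The weak site within the alpha cluster ranked 39061 in replicate 1, just past the 38384 peaks used, and 21495 in replicate 2.

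Genes of other lineages were mixed. Megakaryocyte markers had a site in 9 of 12 cases (adjusted p = 0.248, Fisher's exact test), with Gp1ba, Gp5, Gp9 and Itgb3, all genes of platelet receptors, at ranks 323, 917, 1032 and 1264, and none at Gp6 or Mpl. Within the 5000 strongest sites this list passed, with 8 of 12 genes (adjusted p = 1.57e-06, Fisher's exact test). Mast cell and basophil markers (7 of 11), led by Gata2, Ms4a2, Cpa3 and Fcer1a, lymphoid markers (11 of 18), led by Vpreb1 and Igll1, which share a site at rank 4814, and myeloid markers (5 of 14), led by Cebpe at rank 166 and Csf3r at rank 1789, did not pass. Nor did proviral and ETS leukemia genes (10 of 14), with Nfe2 at rank 796 and Trp53 at rank 4636, cell cycle genes (10 of 15), with Rb1 at rank 1691 and E2f2 at rank 2820, or E protein partners and inhibitors (11 of 18). Muscle genes and neural genes had a site in 2 of 12 cases each (16.7%, adjusted p = 0.0525 for each, Fisher's exact test), with none at Ckm, Acta1, Ascl1 or Atoh1. Liver genes had a site in 3 of 12, with none at Alb or Cyp7a1. No list was below background after adjustment, and 8 of the 17 lists had an unadjusted p below 0.05, muscle and neural genes among them.

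**Figure D2:**
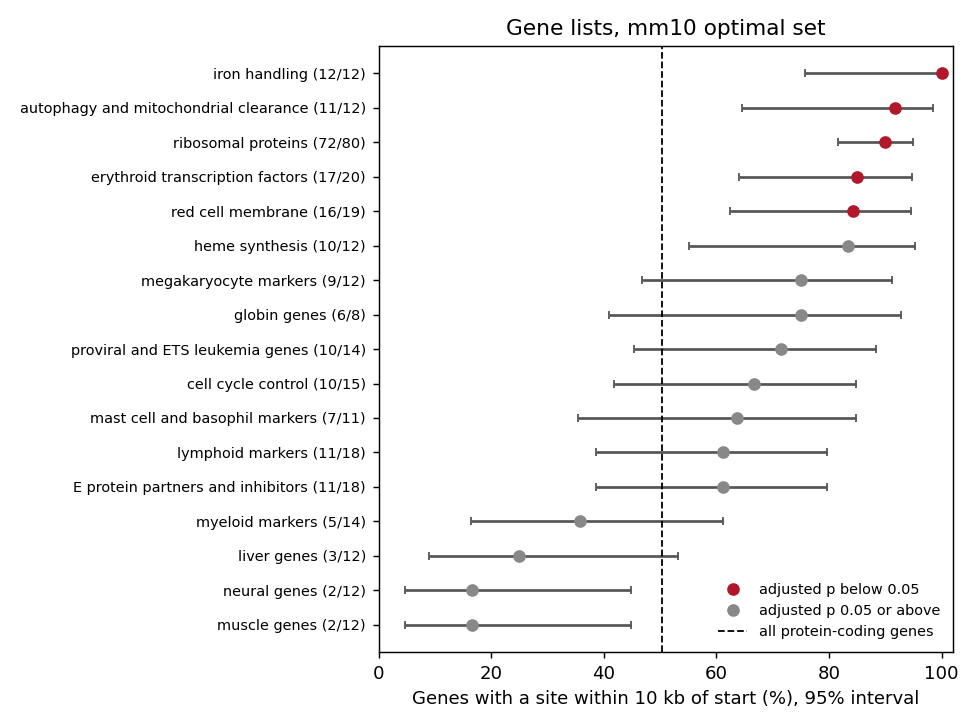
Share of each gene list with a site of the optimal set within 10 kb of a start site, in percent. Points give the share, bars the Wilson 95% interval over genes, and the dashed line all protein-coding genes (50.3%). Red points mark the 5 lists past the adjusted threshold.

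These gene counts have 2 limits. On mm10 the start site was the outer end of each gene, and other starts were not searched: Ank1, Erg, Bcl2l1 and Cbfa2t2 had no site at that end but 7, 12, 8 and 6 sites in the gene and 10 kb around it. With all transcript starts on mm9, Ank1 and Cbfa2t2 had 5 and 1 sites within 10 kb, and Erg and Bcl2l1 had 0. For Gata1, Cbfa2t3, Alad, Add2, Epor and Rpl36a the mm10 lists gave no site within 10 kb, whereas the mm9 list gave between 3 and 9 for each gene, so their mm10 counts are not read as absence of binding, and they lower the shares above, Alad being 1 of the 2 heme synthesis genes without a site. The full relaxed lists had few entries there, between 0 and 7 within 10 kb of each start in any list, and none for Cbfa2t3 and Rpl36a. Sites around these starts were not analysed here on mm10. In all, 917 genes had a site within 10 kb of a start on mm9 but none on mm10, and how many of these are affected in the same way was not separated from the use of outer gene ends. On the mm9 list all 20 erythroid transcription factors, all 19 membrane genes and 11 of 12 heme synthesis genes had a site, while autophagy genes (8 of 12, adjusted p = 0.172, Fisher's exact test) did not pass there. The autophagy call was also lost among the 5000 strongest sites (adjusted p = 0.135), against genes near any relaxed peak (0.0782) and with a distance of 50 kb (0.0509, Fisher's exact tests). At 50 kb the membrane, iron and erythroid transcription factor lists lost their call as well (adjusted p = 0.0509 each, Fisher's exact test). Ribosomal protein genes (adjusted p = 2.54e-07) and cell cycle genes (0.0489) were above background, and neural genes below it (0.0489, Fisher's exact tests). With only sites over 1 kb from every start site, 8 lists were above background.

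Start sites of protein-coding genes were a common place of binding. On mm10, 21.2% of optimal sites lay within 1 kb of a start site (Wilson 95% interval 20.8% to 21.6%), against a mean of 1.68% in 100 shuffles, a 12.7-fold difference (one-sided permutation p = 0.0099, the smallest that 100 shuffles can give). The lists of the replicates gave 23.6% for replicate 1 and 19.6% for replicate 2 (mean 21.6% ± 2.85, SD, n = 2). Among the 5000 strongest sites the share was 6.30%, so stronger sites were more often away from start sites. On mm9, where transcripts were used in full, 25.7% of sites were at promoters, 36.3% in introns and 35.6% intergenic. Intergenic sequence held 0.601 times as many sites as in the shuffles, and introns 1.04 times (two-sided permutation p = 0.0198 for each, the smallest possible). Coding exons held 0.832% of sites and 3' untranslated regions 1.1%.

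The sequence at the summits was dominated by GATA motifs, the sites of GATA1, a partner of E protein complexes in erythroid cells. In the mm9 list, 64.4% of summits had WGATAR within 50 bp (Wilson 95% interval 63.8% to 65.0%), against 15.3% of flanks 300 bp away, a ratio of 4.2 (bootstrap 95% interval 4.12 to 4.30). The E-box forms CAGCTG, CAGATG and CAGGTG together, written CAGVTG, were at 24.5% of summits against 17.1% of flanks, a ratio of 1.44 (1.4 to 1.48). Of the 10 E-box forms, 4 were higher at summits by an exact McNemar test with Benjamini-Hochberg adjustment, 3 were lower and 3 did not pass. CAGCTG had the highest ratio, 2.14, then CACGTG with 1.70 (1.21 and no longer past the threshold in the 5000 strongest sites of the mm9 list), CAACTG with 1.54 and CAGATG with 1.5, whereas CACCTG, which reads CAGGTG on the other strand, was at 7.19% of summits and 7.03% of flanks. CACCTG differed by class of site, with a ratio of 0.75 within 1 kb of a start site and 1.21 over 10 kb from any. Both passed the adjusted exact McNemar test. CACGTG had ratios of 2.37 and 1.37 in these classes and did not pass in the second. In all, 47.5% of sites had WGATAR without CAGVTG, 7.62% had CAGVTG without WGATAR, 16.9% had both and 28.0% had neither.

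**Figure D3:**
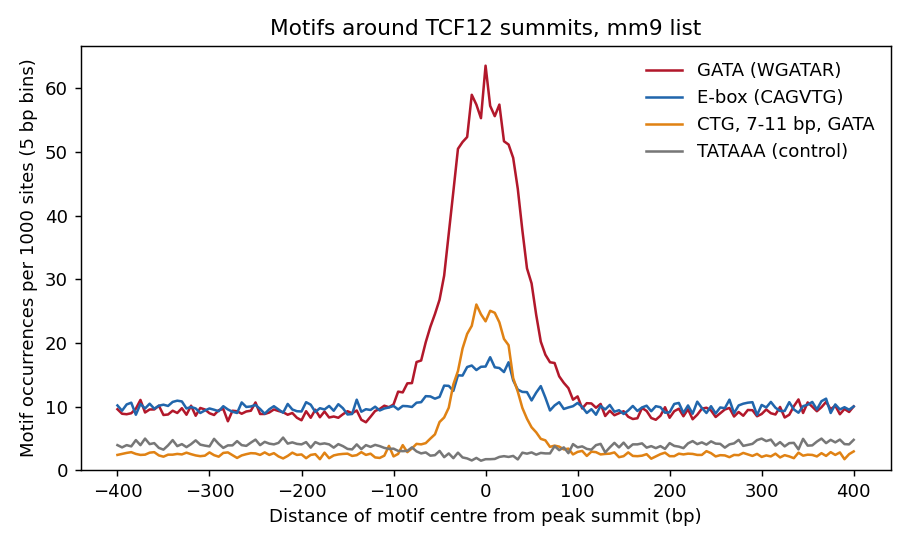
Motif occurrences per 1000 sites in 5 bp bins against the distance of the motif centre from the summit in bp, mm9 list. Lines show WGATAR, CAGVTG, CTG and GATA 7 to 11 bp apart, and TATAAA as a control. WGATAR, found at 64.4% of sites within 50 bp, peaks at the summit, and TATAAA dips there.

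CTG, the end of many E-boxes, and GATA were found at a fixed distance. The order CTG then GATA with 9 bp between them was at 3831 sites, against a mean of 1259 for the other spacers from 0 to 30 bp, a ratio of 3.04 (exact binomial test, adjusted p = 1e-300, the smallest value written). Spacers of 8 and 10 bp were also raised, with 2325 and 1878 sites. Those of 7 and 11 bp, with 1169 and 1118 sites, were below the mean of the others. The flanks had a mean of 428 sites at 9 bp, and in the reverse order the counts ran from 967 to 1356 outside a spacer of 0. The composite element with 7 to 11 bp, chosen before the data were examined, was at 29.2% of summits and 3.94% of flanks, a ratio of 7.41 (7.08 to 7.75). This ratio also reflects GATA itself, which was raised at summits. At a spacer of 12 bp, which was not raised, 1102 sites had the pair around summits and 458 in the flanks. Of sites with WGATAR, 50.7% had no CANNTG of any form within 50 bp. Among all sites, CANNTG was at 45.4% of summits and 38.4% of flanks, so sites with WGATAR did not lack it more often.

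**Figure D4:**
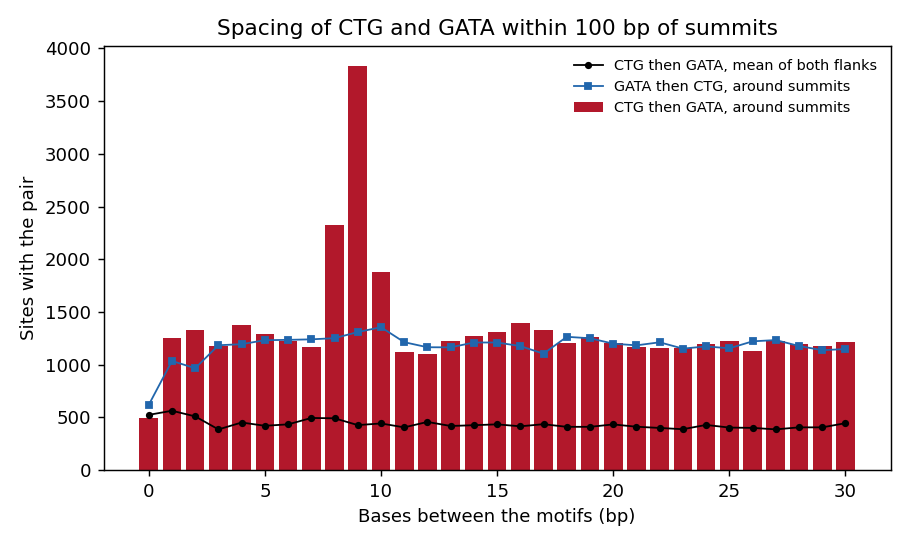
Number of sites with CTG and GATA on the same strand within 100 bp of the summit, by the bases between them in bp, mm9 list. Bars show CTG then GATA at summits, black points the mean of the flanks and blue points the reverse order. The bar at 9 bp reaches 3831 sites.

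Motifs of other blood factors were also raised at summits. PU.1 (GAGGAAGT), whose gene is activated by proviral insertion in many erythroleukemias, was at 3.25% of summits and 0.564% of flanks, a ratio of 5.77. RUNX was at 9.57% with a ratio of 2.34, the general ETS motif at 40.5% with 1.59, KLF at 8.17% with 1.81, AP-1 at 3.11% with 1.83, and the longer NFE2 motif at 0.517% with 5.24. CTCF (ratio 2.41) and NRF1 (ratio 10.2, at 66 sites) were raised as well, so that 8 of the 9 other motifs were higher by the adjusted exact McNemar test, and the control TATAAA was lower (ratio 0.528). Among the 5000 strongest sites of the mm9 list, 6 of the 9 were higher, and CTCF was lower at summits than in flanks (ratio 0.343). Of the 66 sites with NRF1, 63 were at promoters.

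Promoter and distal sites differed in sequence. WGATAR was at 21.4% of the 6526 sites within 1 kb of a start site and at 80.2% of the 12099 sites over 10 kb from any, an odds ratio of 0.0672 (two-sided Fisher's exact test, adjusted p = 1e-300, the smallest value written). The composite element was at 9.88% and 36.4% (odds ratio 0.192), and CAGVTG at 16.5% and 27.0% (odds ratio 0.533, adjusted p = 1.49e-61, Fisher's exact test). The composite element holds GATA, so its difference partly restates that in WGATAR. The pairing itself was not tested between the classes. Promoter summits had WGATAR more often than their own flanks (9.09%), while CAGVTG was at 16% of those flanks and did not pass. Its forms differed there: CAGCTG was raised (ratio 1.59), CAGATG did not pass and CACCTG, the other strand of CAGGTG, was lower (0.75). Among the 5000 strongest sites of the mm9 list the difference in CAGVTG was not found (29.2% and 28.2%, odds ratio 1.05, adjusted p = 0.673, Fisher's exact test), while that in WGATAR was (odds ratio 0.202). The composite element was at 43.4% and 49.9% there, an odds ratio of 0.769 (adjusted p = 0.00999, Fisher's exact test).

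Motif content rose with peak strength. The mm9 list was divided by signal value into 10 bins of equal size. In the strongest bin 90.8% of sites had WGATAR and 55.3% the composite element, against 49.8% and 19.2% in the weakest bin, with odds ratios of 9.93 and 5.21. The composite element holds GATA, so these rises are not independent. CAGVTG was at 32.1% and 23.5%, an odds ratio of 1.54 (two-sided Fisher's exact test, adjusted p = 1.19e-11). Promoters made up 8.75% of the strongest bin and 30.9% of the weakest.

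**Figure D5:**
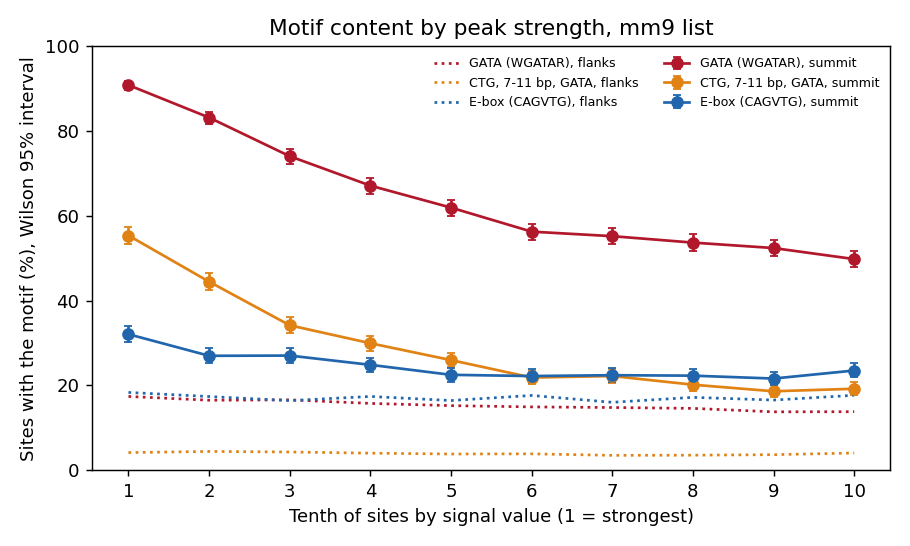
Share of sites with each motif, in percent, by bin of the mm9 list ranked by signal value, from 1, the strongest, to 10. Points give summits with Wilson 95% intervals over sites, dotted lines the flanks. WGATAR falls from 90.8% to 49.8%.

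Sites were unevenly spread over chromosomes. Chromosome 11 had 28.6 optimal sites per Mb, 2.04 times the genome's density, while its density of genes was 1.66 times the genome's. Chromosome X had 6.33 per Mb, 0.452 times the genome's. The mm9 list and the mm10 optimal set differed by at most 0.288 percentage points in any chromosome's share of sites, on chromosome 19. Of 9081 genes with an mm9 site within 10 kb of a start site, 89.9% had one in the optimal set, against 50.6% if the lists were unrelated.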

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

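The explanatory tests below were written down before their results were seen, except the count of sites without a whole E-box and the count of diverged copies, which were chosen after. The chromosome 15 test was first run in another form, and the rule that no other chromosome may pass it was added after its result was seen. The share of whole E-boxes was written for CANNTG and counted as CANCTG. Both signals named first lie in entries that the comparisons of sites did not use. The optimal set held 5 entries on the mitochondrial genome, with signal values from 16.2 to 62.7. The replicate 1 list held 20 such entries, the replicate 2 list 0 and the conservative set 0. Among the 38384 strongest entries of the pooled list, 4592 overlapped no entry of the optimal set, and the highest of them ranked 10653. Of these, 93.6% were present in both replicate lists, against 96.8% of optimal entries in the same range of ranks. Past the 38384 strongest peaks of replicate 1 and of replicate 2 ranked 40% and 35.7% of them, against 21.9% and 14.8% of those optimal entries.

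Promoter sites had far fewer GATA motifs than distal sites. Weaker peaks at promoters are not the whole of it, since after matching on 10 bins of signal the odds ratio of WGATAR was 0.081. GC-rich sequence with fewer GATA words by chance stays open. The ratio of summit to flank share of WGATAR at promoters was 0.5406 of that at distal sites. This would argue against it only if flanks matched summits in base composition, which was not compared. Other AT-rich words were mixed. At promoter and distal sites CAAATG had ratios of 0.598 and 0.894, and CATATG of 0.544 and 0.91, while TATAAA and CAATTG had higher ratios at promoters. Whether promoter sites are held by other factors stays open as well. The ETS motif's summit to flank ratio at promoters was 1.087 times that at distal sites, with intervals apart, but NRF1 had too few distal sites to compare.

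CTG and GATA stood at a spacer of 9 bp more often than at others. Near-identical copies of a repeat family cannot account for this, as 0.3132% of the sites shared the element and 10 bp on each side with another site. Nor can copies diverged by up to about 20%: in 2.297% of the sites the element and 50 bp on each side differed from those of another site in at most 35% of positions, whereas 67.1% of the sites were in excess of the mean of the other spacers. Older copies, and copies with gaps between them, would be missed and stay open. Whole E-boxes do not account for it either. The prediction named CANNTG, and an E-box that holds the element's CTG reads CANCTG, so that form was counted. It was 1.247 times as common in these elements as at spacers of 12 to 30 bp. This lies between the limits written in advance, so the share alone decides nothing. The 3409 sites without CANCTG were still 2.961 times the mean of the other spacers (95% interval 2.86 to 3.07). No biological explanation was tested.

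Relaxed peaks were dense on chromosome 15. Outside the optimal set the median of its bins of 1 Mb was 1.89 times that of bins with equal gene numbers elsewhere in the replicate 1 list (bootstrap 95% interval 1.72 to 2.11) and 1.95 times in the replicate 2 list (1.58 to 2.36), and 1.82 and 1.86 times without X. This count restates the pattern, so whether the line has extra copies of the chromosome stays open. More genes or optimal sites are argued against for the bins that could be matched, since the ratios were still 1.589 and 1.85 after matching on both. This matching covered 50 bins of chromosome 15, against 97 with genes alone. Weaker binding sites were not matched. Chromosome 11 gave 1.77 and 1.58 in the first comparison and 1.62 and 1.31 after matching on both, and no copy number was measured here.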

How the results depend on the processing

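Alternatives on the mm9 list with its transcript starts, on the 5000 strongest sites of the mm9 list, on sites over 1 kb from every start site and on genes shared by both builds were chosen after seeing the data. The others were fixed before the data were examined. Of these the conservative set, the 5000 strongest optimal sites and the replicates left out were not run for motif results, nor the conservative set for annotation, nor motifs inside against outside the optimal set, because sequence was at hand for mm9 only. The filter on soft-masked repeats was not run because the genome sequence used is not soft-masked. No paired analysis was possible because there was a single group. Depth is unknown, and the number of genes in each list limits its test. The cause of the changes below was not tested.

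Promoter share, the WGATAR, CAGVTG and spacing results, and the odds ratios of WGATAR and the composite element, kept their direction and side of the threshold under every alternative run. The promoter share ranged from 6.30% to 25.7%, the GATA ratio from 2.51 to 5.79, the CAGVTG ratio from 1.23 to 1.66, and the ratio at 9 bp from 3.04 to 4.12. Replicate sharing was 64.2% with reciprocal overlap of 50%, 55.0% with summits within 50 bp, 71.7% for the size of the conservative set and 74.6% for the 10000 strongest peaks. Rho was 0.733 in the conservative set and 0.670 in the 5000 strongest sites. The conservative share was 77.5% with reciprocal overlap, and genes shared between builds 88.7% with the conservative set.

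In the 5000 strongest mm9 sites the odds ratio of CAGVTG at promoters reversed to 1.05 (adjusted p = 0.673, Fisher's exact test), 5' untranslated regions fell to 0.040% of sites, coding exons at 0.980% no longer passed, other exons at 0.420% passed, and the CTCF ratio reversed to 0.343. The odds ratio of the composite element moved to 0.769 there, and the forms CACGTG (ratio 1.21, adjusted p = 0.231, exact McNemar test), CAAATG (0.887) and CATATG (0.965) no longer passed. Ratios of CAAGTG reversed to 1.02 within 25 bp, and of CACATG and CACCTG to 0.987 and 0.955 within 100 bp, where CACCTG passed, while CATATG did not pass within 25 bp (0.859).

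Lists above background numbered 2 at a distance of 50 kb and 8 with only sites over 1 kb from start sites. A list is called reversed below where its share crossed the background share of that setting. No such list passed the threshold in the main result or in that setting. For myeloid markers the background was 71.0% at 50 kb, 48.7% in the conservative set and 7.49% in the 5000 strongest sites. Leaving out each replicate gave 5 and 7 lists, with globin genes from 25% to 100%, heme synthesis 83.3% in both cases, myeloid markers 35.7% to 50%, lymphoid markers 44.4% to 61.1% and muscle genes 8.33% to 25%. The calls of 3 lists depended on the replicate, with adjusted p in the replicate 1 and 2 lists of 0.101 and 0.0435 for heme synthesis, 0.211 and 0.00967 for globin genes and 0.124 and 0.0156 for muscle genes (Fisher's exact tests). At 50 kb, red cell membrane (94.7%), iron handling (100%), erythroid transcription factors (95%) and autophagy (100%) lost their call, cell cycle (100%) and neural genes (33.3%) gained a call, and myeloid markers reversed (78.6%). At 1 kb, globin genes (0%) and lymphoid markers (11.1%) reversed, and myeloid (0%), muscle (0%) and neural genes (0%) passed. In the conservative set heme synthesis (83.3%), cell cycle (80%) and muscle genes (8.33%) passed and myeloid markers reversed (50%). In the 5000 strongest sites heme synthesis (75%) and megakaryocyte markers (66.7%) passed, autophagy (25%) did not and myeloid markers reversed (14.3%). With genes near any relaxed peak as background, heme synthesis (100%) and neural genes (20%) passed and autophagy (91.7%) did not. With matched random lists globin genes (75%), several of which share the same site, passed. With only sites over 1 kb from start sites, globin (75%), heme synthesis (75%) and megakaryocyte lists (66.7%) passed. On the mm9 list heme synthesis (91.7%), cell cycle (73.3%), megakaryocyte (83.3%), muscle (0%) and neural genes (8.33%) passed, autophagy (66.7%) did not and lymphoid markers reversed (29.4%).

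Some named genes had no site in the optimal set but 1 or more in other lists. Gabarapl1, Bcl2l1 and Mcpt1 had them in the conservative set and in both replicate lists. Cebpa had them in the conservative set and the replicate 2 list. Mpl, Hbb-bh1 and Hbb-bh2 had them in the replicate 2 list and Cbfa2t2 in the replicate 1 list. Conversely, Chrna1 and Neurog2 had a site in the optimal set and the replicate 1 list. They had none in the conservative set or the replicate 2 list. Each was 1 of the 2 genes with a site in its list, muscle and neural genes. Hba-a1, Hba-a2, Hbq1a and Hbq1b had an optimal site but none in the replicate 1 list.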

Other observations

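Megakaryocyte markers had a site over 1 kb from every start site in 8 of 12 genes (adjusted p = 0.0173, Fisher's exact test), against 28.7% of other genes, an alternative chosen after seeing the data. Ribosomal protein genes, at 90.0% with all sites, had such a site in 36 of 80 cases (45%, adjusted p = 0.00637, Fisher's exact test). The difference between these lists was not tested.

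Of genes with a site near a start site on mm9, 917 had none near the outer gene end on mm10, and 635 of these (69.2%) had a site in the gene and 10 kb around it. Of 9070 genes with none near a start on either build, 16% had such a site. Another 2066 genes had a site near the start on mm10 only. The reasons for these differences were not tested.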
